A study of Drosophila melanogaster with 12 samples.

How the data were processed

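RNA from heads of male Drosophila melanogaster of the Canton-S strain was hybridised to single-colour Affymetrix arrays, 1 array per sample and 12 samples. Per the labels, males were 5 days old, came from populations at generation 21 of selection, were frozen in groups within the same short time of day, and RNA was extracted with Trizol and labelled with biotin by the standard Affymetrix protocol. The samples fall into 4 populations of 3 arrays: aggressive I and II, selected for more male aggression, and neutral I and II, the reference populations. Groups and replicate numbers were taken from the sample titles. The line label of 2 arrays of neutral I names the strain without the word selected that the other arrays carry, and those arrays were kept in their titled group.

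The deposited values are probe set intensities from MAS5, the Affymetrix signal algorithm, per the submitters' processing notes, with its version not given in the sources used here. They are on a linear scale, all above 0, for 14010 probe sets. From the values, each array had been scaled to the same trimmed mean, 2500 after setting aside the lowest and highest 2% of probe sets, so that differences in total RNA between arrays are not measured. The arrays had median signal between 962.4 and 1050. Only these summarised intensities were used, and scanner images, detection calls and single probe values were not analysed here. For the comparison of regimes, the precision is limited by the 2 populations per regime, beside the 3 arrays per population. The median SE of a log2 difference between regimes was 0.14. The fit behind this SE used the same correlation between arrays of a population, 0.0645, for all probe sets. The SE may therefore understate the spread between populations where a probe set drifts.

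Probe sets were named with the array's annotation table and current symbols from the Drosophila melanogaster RefSeq table (assembly Release 6 plus ISO1 MT), matched through Entrez identifiers. Of 13966 probe sets that are not controls, 12443 had 1 gene, 327 had several and were not named, and 1196 had none. Of those with 1 gene, 12394 matched the RefSeq table, and 0 symbols changed. The intensity table names no genome build, so no coordinates are given, and the RefSeq table was used only for names and for which genes neighbour each other.

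Values were transformed as log2(intensity + 94.6), where 94.6 is the 10th percentile of all intensities, and centred on the median of each array. Fold changes are on this scale, which understates changes of dim probe sets, while signal means and SDs in the text are the deposited intensities. The 44 control probe sets were left out of the tests, and the 8379 probe sets with a mean above the 40th percentile were kept. Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0, and Benjamini-Hochberg adjustment at a threshold of 0.05. The regime comparison treated population as a random block (duplicateCorrelation, consensus correlation 0.0645, prior degrees of freedom 3.25), since the selected unit is the population and there are 2 per regime. Comparisons of single populations, the interaction of regime with pair, and the genes passing in all 4 aggressive against neutral pairs used fixed population means over all 12 arrays, whose error is the spread between arrays. As the populations can be split 2 against 2 in only 3 ways, no permutation of populations gives a p below 0.333.

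The 24 gene lists, of pathways and of markers of tissues a head sample could hold, were tested with limma's cameraPR on the moderated t of 6871 genes, each represented by its probe set with the highest mean, with a preset correlation of 0.01 and again with the correlation estimated from the arrays. Lists needed 5 or more kept genes. After the list results had been seen, 8 symbols caught by name patterns though they are of another kind (SerT and the Npc2 genes in the midgut list, Acp1 and Acp65Aa in the testis list) were taken out, and neither list passed either way. The genes named in the text follow a rule: among called genes with both aggressive means on the same side of both neutral means, up to 12 that rose and 12 that fell, Cyp6a20 whatever its result, up to 4 genes per list by smallest p, and for each within-regime comparison the 5 with the largest difference in each direction. The tests, lists, rule and alternatives were fixed before the data were examined, except where stated. The adjustment of single genes over their list alone was not among the tests fixed beforehand. It was made within each of the 24 lists, with no adjustment across lists.

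The tests were tried on simulated arrays of the same 8379 probe sets for the comparison of aggressive with neutral, with 200 probe sets changed and 3 runs per setting. Even drift was set in proportion to the spread of each probe set between arrays. With it, the random block recovered 55.7%, 91.5% and 98% of changes of 0.5, 1 and 1.5 on the log2 scale. Of its calls, 11.4% were false. When 5% of probe sets had extra drift between populations with an SD of 0.7, 35.7% of its calls were false. Fixed population means gave 10.5% and 56.4% false calls and 1 mean per population 3.28% and 8.64%, the last recovering 2.49% and 74.1% of changes of 0.5 and 1 with even drift. With no changes and no drift simulated, each of these fits made 0 calls, and drift without changes was not simulated. The adjusted p of the random block therefore understates the share of false calls where populations drift. These shares depend on the 200 changes planted. With extra drift the random block made 256 calls on average, 91.7 of them false, against 16 calls in the real data. The simulated shares therefore do not carry over to the real calls.

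Array quality was read from 9 bacterial spike-in probe sets, from 3' to 5' signal differences of 3 control genes, from 18S rRNA signal and from the spread of each array about its population mean. Aggressive I array 2 and neutral I array 3 had the lowest mean correlation with the other arrays (0.952 and 0.951, against 0.957 to 0.964 for the rest). No arrays held identical values. Alternatives covered scaling, the pseudocount, the filter, the variance model, the handling of population, a block for replicate number, leaving out each population or array, and, added after the data had been seen, array quality weights, leaving out both arrays named above, and list tests on 1 mean per population or on fixed population means. Plots were made with matplotlib 3.10.9.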

Results

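Gene expression was measured in heads of 5-day-old male Drosophila melanogaster of the Canton-S strain, a standard laboratory wild type, after 21 generations of selection on male fighting. The comparison asks which head transcripts set flies selected for more aggression apart from reference flies. The populations are named here aggressive I, aggressive II, neutral I and neutral II, with 3 Affymetrix arrays from each of the 4 populations and 12 arrays in all. The neutral populations had been selected for less aggression and, by the study's own description, showed no significant response. Median MAS5 signal per array lay between 962.4 and 1050, and arrays of the same population correlated with a median r of 0.962 over 8379 probe sets, against 0.957 for arrays of different populations of the same regime and 0.959 for arrays of different regimes. The labels do not say whether the arrays of a population came from separate cultures, so p-values that rest on arrays alone may reflect technical spread.

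With the 2 populations of each regime pooled, aggressive heads differed from neutral heads in 16 of 8379 probe sets, of which 8 rose and 8 fell. The balance depended on the setting, with 9 that rose and 25 that fell without aggressive I, 22 and 13 with a trended and robust variance, and 16 and 9 with a filter at the 60th percentile. CG16978 rose most, by 2.80-fold (log2 difference 1.48, SE 0.17, limma adjusted p = 0.00473). Its signal was 7557 ± 249.5 (SD, n = 3) in aggressive I and 6345 ± 1006 in aggressive II. It was 3119 ± 298 in neutral I and 1906 ± 172.7 in neutral II. PGRP-SC2 (CG14745), a peptidoglycan recognition protein that breaks down bacterial cell wall fragments, fell most. Its signal was 690.5 ± 259.1 and 400.6 ± 16.2 in aggressive I and II, against 1864 ± 286.8 and 2199 ± 362.9 in neutral I and II (SD, n = 3). The level was 3.40 times higher in the neutral populations (log2 difference -1.77, SE 0.22, limma adjusted p = 0.00631).

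**Figure D1:**
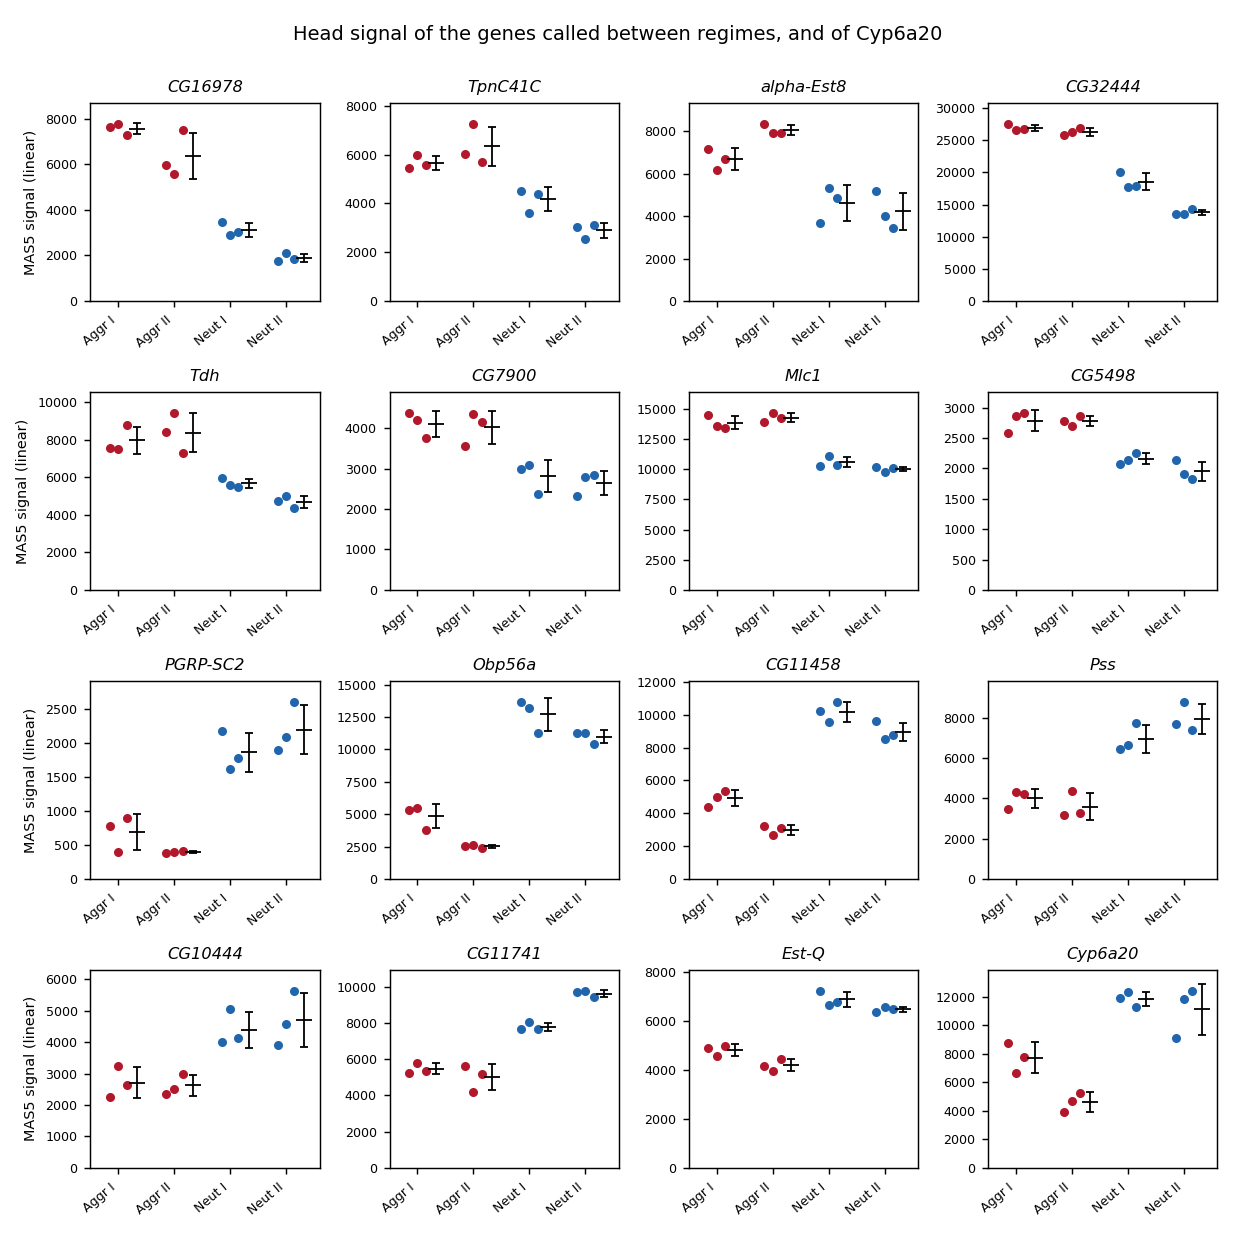
MAS5 signal (linear, y axis from 0) of the 15 named genes called between regimes and of Cyp6a20, in the 4 populations (x axis). Red points are aggressive arrays and blue points neutral arrays, and black marks are the mean ± SD of 3 arrays. For each of the 15 called genes, all 6 aggressive arrays lie on the same side of all 6 neutral arrays.

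The odorant-binding protein Obp56a (CG11797), a secreted carrier of small hydrophobic ligands, fell to 4887 ± 932.5 in aggressive I and 2514 ± 139.5 in aggressive II, from 12710 ± 1252 in neutral I and 10990 ± 484.8 in neutral II (SD, n = 3). Its log2 difference was -1.71 (SE 0.22, limma adjusted p = 0.00631). CG11458 fell with a log2 difference of -1.28 (SE 0.17, adjusted p = 0.00701). Pss (CG4825), phosphatidylserine synthase, fell with a log2 difference of -0.94 (SE 0.13, adjusted p = 0.00701). Est-Q (CG7529), an esterase, CG10444 and CG11741 also fell, with log2 differences of -0.55, -0.73 and -0.71 (SE 0.087, 0.13 and 0.12). The remaining probe set that fell had no gene name in the tables used here and a log2 difference of -0.77 (SE 0.12, adjusted p = 0.0178).

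Among the genes that rose, 2 encode proteins of the muscle contractile apparatus. TpnC41C (CG2981), a troponin C, was 1.72-fold higher (log2 difference 0.79, SE 0.13, adjusted p = 0.0273), and Mlc1 (CG5596), the myosin alkali light chain, was 1.38-fold higher (log2 difference 0.46, SE 0.070, adjusted p = 0.0178). Mlc1 signal was 13850 ± 540.7 and 14280 ± 363.1 in aggressive I and II, against 10600 ± 441.6 and 10010 ± 195.4 in neutral I and II (SD, n = 3). Of the other genes that rose, CG32444, listed with aldose 1-epimerase among its synonyms, was 1.68-fold higher (log2 difference 0.75, SE 0.10, adjusted p = 0.00708), the alpha-esterase alpha-Est8 (CG1121) 1.69-fold (SE 0.13 on the log2 scale, adjusted p = 0.0427) and Tdh (CG5955) 1.59-fold (SE 0.10, adjusted p = 0.0197). CG7900 was higher by a log2 difference of 0.58 (SE 0.10, adjusted p = 0.0452) and CG5498 1.36-fold higher (log2 difference 0.44, SE 0.078, adjusted p = 0.0429).

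Cyp6a20 (CG10245), a cytochrome P450 chosen for report before the data were examined, did not pass over all genes. Its signal was 7727 ± 1055 in aggressive I and 4605 ± 687.1 in aggressive II, against 11820 ± 502 in neutral I and 11100 ± 1779 in neutral II (SD, n = 3). The log2 difference was -0.91 (SE 0.19, 95% interval -1.33 to -0.50, adjusted p = 0.103). Its adjusted p was 0.0189 over the list alone of 55 cytochrome P450 genes, an adjustment not fixed beforehand. It was 0.00253 over all genes in a fit with fixed population means, which takes its error from the arrays and not from the spread between populations. Over the 29 alternatives the log2 difference of Cyp6a20 ran from -1.31 to -0.52, and the gene passed in 4.

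For all 16 called probe sets, both aggressive population means lay on the same side of both neutral means, and all 6 aggressive arrays on the same side of all 6 neutral arrays. That separation of the 12 arrays was seen in 103 of the 8379 probe sets. The calls depend on how the population enters the error: with fixed population means 68 probe sets passed (35 rose, 33 fell), and with 1 mean per population, 2 against 2, limma called 0, with 400 at an unadjusted p under 0.05 where 419 would come by chance. Leaving out neutral II left 2 calls. Without single arrays the count was 10 without aggressive I array 1, 9 without aggressive I array 3, 8 without aggressive II array 1, 8 without aggressive II array 3, 10 without neutral II array 1 and 7 without neutral II array 3. CG16978, CG32444, PGRP-SC2, Obp56a, CG11458 and Pss passed with each of the 12 arrays left out in turn. Of these, CG16978 alone also passed with each population left out. Without neutral II, PGRP-SC2, Obp56a and CG32444 (adjusted p = 0.112 each), CG11458 (0.121) and Pss (0.126) were lost, with log2 differences of -1.63, -1.79, 0.56, -1.35 and -0.82. Obp56a (adjusted p = 0.0563, log2 difference -1.64) and CG11458 (0.0754, -1.21) were also lost without neutral I, and CG32444 (0.0531, 0.71) without aggressive I. Mlc1 passed in 11 of these fits, being lost without neutral II array 3 (adjusted p = 0.0538), and Tdh in 8. Est-Q passed in 6, alpha-Est8 and CG11741 in 4 each, TpnC41C in 3, CG10444 in 2, CG5498 in 1 and CG7900 in 0. Signal of the bacterial spike-in controls, added to measure hybridization, was also higher on the aggressive arrays (log2 difference 0.21, exact two-sided permutation p = 0.0152, adjusted p = 0.0909 over 6 array measures, n = 6 per regime).

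The same populations can be split 2 against 2 in 2 other ways, neither of which follows the regime. With the same model, aggressive I and neutral I against the others gave 5 calls, and aggressive I and neutral II against the others gave 1 call. With fixed population means these splits gave 25 and 33 calls beside the 68 of the regime split.

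**Figure D2:**
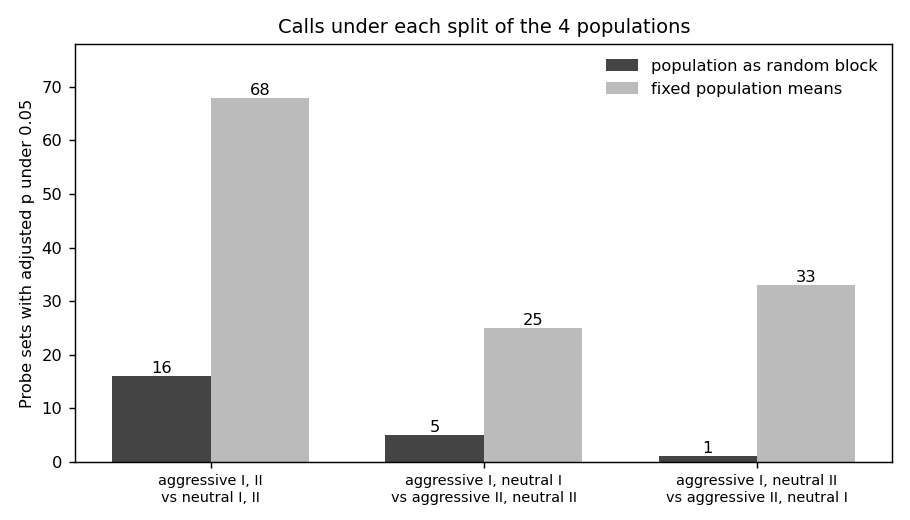
Number of probe sets with an adjusted p under 0.05 (y axis, from 0) for the regime split and the 2 other splits of the 4 populations (x axis). Dark bars are fits with population as a random block (16, 5 and 1) and light bars fits with fixed population means (68, 25 and 33).

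Each aggressive population was also set against each neutral population. In all 4 pairs, 6 genes passed in the same direction: CG16978, CG32444 and CG3397 rose, and PGRP-SC2, Obp56a and CG11458 fell. CG3397 had the widest range over the pairs, from a log2 difference of 0.91 (aggressive II minus neutral I, adjusted p = 0.00778) to 2.81 (aggressive I minus neutral II, SE 0.12). Its signal was 1311 ± 244.4 in neutral II and 4792 ± 255.8 in neutral I against 9586 ± 392 and 8999 ± 458.3 in aggressive I and II (SD, n = 3). It did not pass in the regime comparison (log2 difference 1.86, SE 0.36, adjusted p = 0.0622). Obp56a differed least between aggressive I and neutral II (log2 difference -1.15) and most between aggressive II and neutral I (-2.27). The single pairs gave 33 calls for aggressive I against neutral I (22 rose, 11 fell), 98 for aggressive I against neutral II (50 rose, 48 fell), 25 for aggressive II against neutral I (9 rose, 16 fell) and 64 for aggressive II against neutral II (25 rose, 39 fell). In the aggressive I against neutral I pair the split depended on scaling, with 14 higher and 13 lower after quantile normalization and 15 and 15 without centring, and it turned to 10 and 13 without aggressive I array 3. The near even split of aggressive I against neutral II turned to 48 higher and 54 lower without centring. It was 51 and 55 with the pseudocount at the 25th percentile, and 20 and 28, 24 and 29, and 22 and 35 without aggressive I arrays 1, 2 and 3. The pairs share arrays, and the other population splits gave 3 probe sets (CG42329, CG5397 and a probe set with no gene name) and 2 genes (Lsp2 and Obp99b) that passed in all 4 of their pairs. Without aggressive I array 2 and neutral I array 3, which had the lowest mean correlation with the other arrays, only 1 gene passed in all 4 pairs, and without neutral I array 1 there were 3. Without single arrays the counts of the single pairs went as low as 18 (aggressive I against neutral I, without neutral I array 3), 36 (aggressive I against neutral II, without neutral II array 2), 13 (aggressive II against neutral I, without neutral I array 1) and 36 (aggressive II against neutral II, without neutral II array 2).

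Over all 8379 probe sets, the difference in the I pair did not predict the difference in the II pair, which shares no array with it (Pearson r = 0.0071, Spearman rho = -0.0099, across probe sets, which are not independent replicates). The 2 differences had the same sign for 48.2% of probe sets. The crossed pairs, aggressive I with neutral II and aggressive II with neutral I, gave r = 0.0041, and the pairs within regimes 0.0031.

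Of 24 gene lists fixed before the data were examined, 5 passed in the regime comparison with a preset correlation between genes of 0.01, and 0 passed with an estimated correlation. Genes of oxidative phosphorylation were higher on average in the aggressive heads (60 genes, median log2 difference 0.11, 52 above 0, adjusted p = 6.12e-06, and adjusted p = 0.479 with an estimated correlation), yet none of the 60 passed singly. ND-20 (log2 difference 0.22, SE 0.091) and ATPsynCF6 (0.20, SE 0.078) had among the smallest p-values. The mean log2 difference of the oxidative phosphorylation list, 0.10, ran from 0.055 to 0.13 over the alternatives. Cytosolic ribosomal protein genes were likewise higher (27 genes, median 0.12, 26 above 0, adjusted p = 0.000236, and adjusted p = 0.479 with an estimated correlation), with RpS20 at 0.25 (SE 0.11) and RpS18 at 0.21 (SE 0.10), and 0 of 27 passed singly. After quantile normalization the ribosomal list no longer passed (mean log2 difference 0.0055, adjusted p = 0.94). Both lists differed least between aggressive II and neutral II, with medians of 0.011 (ribosomal protein) and -0.024 (oxidative phosphorylation), and most between aggressive I and neutral I, with medians of 0.23 and 0.27.

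Muscle markers passed as a list (16 genes, median log2 difference 0.060, 11 above 0, adjusted p = 0.00286, and adjusted p = 0.12 with an estimated correlation). For aggressive I minus neutral I and II their medians were 0.0035 and -0.0034. For aggressive II minus neutral I and II they were 0.14 and 0.12, so the difference lay mostly in aggressive II. In the list test on 1 mean per population the muscle list did not pass (adjusted p = 0.105). Of the 16, Mlc1 and TpnC41C rose, over all genes and adjusted over the list alone, and 14 did not pass, among them Mlc2 (log2 difference 0.16, SE 0.078) and Zasp66 (0.24, SE 0.12). Of these 14, 9 were above 0 and 0 had an unadjusted limma p under 0.05. The list was not tested without Mlc1 and TpnC41C, so its pass is not separate from the calls of these genes. Glutathione S-transferase genes, which detoxify xenobiotics, were higher on average (29 genes, median 0.14, 20 above 0, adjusted p = 0.048, and adjusted p = 0.229 with an estimated correlation). The list median was 0.24 and 0.18 for aggressive I minus neutral I and II. It was only 0.056 and 0.021 for aggressive II minus the same populations. None of the 29 passed over all genes, and 3 rose and 1 fell when adjusted over the list alone: GstD2 (log2 difference 0.82, SE 0.18), GstZ2 (0.37, SE 0.11) and GstE8 (0.28, SE 0.086) were higher and GstD3 (-0.97, SE 0.23) lower. This list was lost in 8 of the 12 fits without 1 array and without aggressive I array 2 and neutral I array 3 together (adjusted p = 0.0688). It was also lost after quantile normalization (adjusted p = 0.0898), without centring (0.0507), with no filter (0.0507), with a filter at the 60th percentile (0.0701) and with fixed population means (0.0707). Heat shock protein genes, mostly chaperones, were lower (9 genes, median -0.056, 1 above 0, adjusted p = 0.0252, and adjusted p = 0.12 with an estimated correlation), with Hsc70-4 at -0.22 (SE 0.082) and Hsp60A at -0.26 (SE 0.098), and none passed singly. It was lost without aggressive II array 1 (adjusted p = 0.106), neutral I array 3 (0.0626) or neutral II array 3 (0.0628), without aggressive I array 2 and neutral I array 3 together (0.0688), and with fixed population means (0.0561). With no filter on dim probe sets its mean log2 difference went from -0.11 to -0.022 (adjusted p = 0.248).

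**Figure D3:**
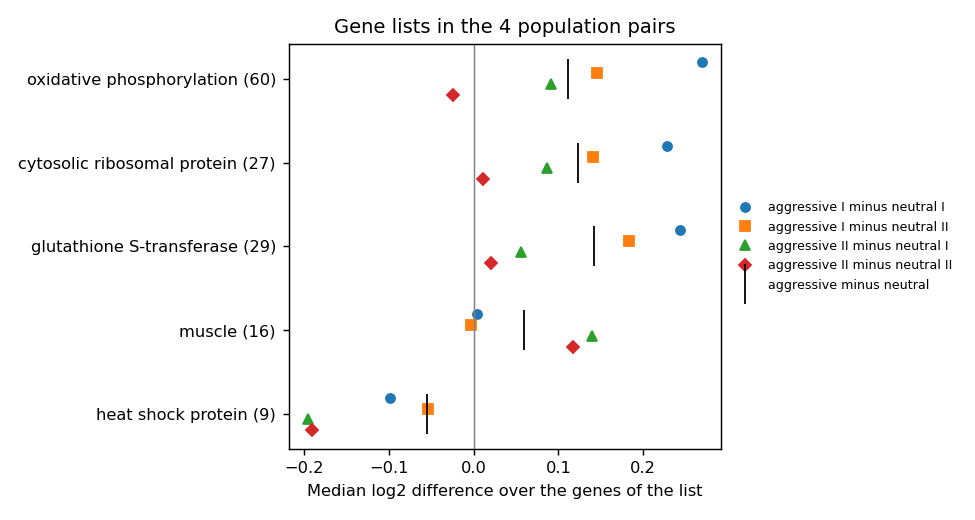
Median log2 difference over the genes of each of the 5 lists that passed (x axis) for the 4 population pairs (coloured symbols) and the regime comparison (black bar), with the number of genes in brackets. The oxidative phosphorylation and ribosomal protein medians run from 0.27 and 0.23 in aggressive I minus neutral I to -0.024 and 0.011 in aggressive II minus neutral II.

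18S rRNA signal, a sign of the RNA sample, was highest in aggressive I, the population with the highest means of the oxidative phosphorylation and ribosomal protein lists (mean log2 14.45 against 13.11 in aggressive II, 13.20 in neutral I and 13.22 in neutral II). This concerns population means. Within aggressive I, array 2 had the highest 18S rRNA signal (38320) and the lowest oxidative phosphorylation mean (log2 14.495 against 14.511 and 14.562). Whether they vary together from array to array was not tested.

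The other 19 lists did not pass in the regime comparison. Circadian clock genes had the smallest adjusted p among them (11 genes, median -0.097, adjusted p = 0.0584), and vri, a clock repressor, fell when adjusted over the list alone (log2 difference -0.38, SE 0.097, adjusted p over all genes 0.239). The clock gene per was at -0.35 (SE 0.12) and tim at -0.42 (SE 0.17). Photoreceptor and phototransduction genes gave adjusted p = 0.0864 (20 genes), with 2 rising when adjusted over the list alone, the channel gene trpl (0.32, SE 0.091) and Gbeta76C (0.26, SE 0.075). Juvenile hormone genes gave adjusted p = 0.141 (6 genes), with the receptor gene gce lower (-0.55, SE 0.12) and past the threshold when adjusted over the list alone. The neuropeptide list gave adjusted p = 0.805 (18 genes), with Dh44, diuretic hormone 44, at -0.60 (SE 0.12, adjusted p = 0.0707 over all genes), past the threshold when adjusted over the list alone. Genes of biogenic amine synthesis, transport and reception gave adjusted p = 0.419 (20 genes), with Tbh, which makes octopamine, at -0.42 (SE 0.15), DAT at -0.32 (SE 0.16) and SerT at -0.25 (SE 0.15), and none passed either way.

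Immune effector and recognition genes gave adjusted p = 0.227 (43 genes, 1 fell, PGRP-SC2). Adjusted over the list alone, Drs, the antifungal peptide drosomycin, also passed (log2 difference 0.75, SE 0.14, adjusted p = 0.0571 over all genes). Its signal was 7118 ± 557.5 and 5177 ± 555.2 in aggressive I and II against 3589 ± 153.7 and 3674 ± 493.3 in neutral I and II (SD, n = 3). The odorant-binding protein list gave adjusted p = 0.419 (19 genes, 1 fell, Obp56a, over all genes and adjusted over the list alone), and the odorant, gustatory and ionotropic receptors gave adjusted p = 0.981 (11 genes). The cytochrome P450 list gave adjusted p = 0.805 (55 genes, 0 passing over all genes and 1 lower adjusted over the list alone, Cyp6a20), UDP-glycosyltransferases 0.822 (14 genes). Sex determination genes gave 0.722 (7 genes), cuticular hydrocarbon synthesis 0.805 (5 genes, with Desat2 at 0.22, SE 0.14) and eye pigment genes 0.981 (15 genes). Among markers of other tissues that a head sample could hold, neuron markers gave adjusted p = 0.381 (12 genes, with Gad1 at -0.33, SE 0.099), glia 0.302 (12 genes), fat body and female genes 0.142 (11 genes), testis and accessory gland 0.822 (7 genes) and midgut digestive enzymes 0.805 (18 genes). Cuticle protein genes gave adjusted p = 0.822 (47 genes, 0 passing over all genes, and 1 higher and 2 lower adjusted over the list alone). Ccp84Ag was at -1.43 (SE 0.32), Cpr11B at -0.38 (SE 0.098) and Cpr76Bc at 0.33 (SE 0.088).

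Populations of the same regime also differed from each other. Between aggressive I and aggressive II, 49 of 8379 probe sets passed, 35 higher in I and 14 higher in II. CG3984 was 13.1-fold higher in aggressive I (5755 ± 396.2 against 420.5 ± 296.8, SD, n = 3, log2 difference 3.71, SE 0.34, limma adjusted p = 0.000548), CG16926 4.89-fold (18900 ± 1296 against 3950 ± 672.2) and the odorant-binding protein gene Obp99b 4.29-fold (39520 ± 2176 against 9460 ± 838.1, log2 difference 2.10, SE 0.10). Pepck2, a phosphoenolpyruvate carboxykinase of gluconeogenesis, was 3.68-fold higher in aggressive I (4984 ± 531.2 against 1325 ± 51.2), and CG8661 2.68-fold. Higher in aggressive II were the odorant-binding protein gene Obp83b (1153 ± 136.7 against 150.9 ± 47.2, log2 difference -2.31 for I minus II, SE 0.17, adjusted p = 7.14e-05), CG5397 (3.13-fold), Sos, a guanine nucleotide exchange factor for Ras (2.58-fold), CG13239 (2.37-fold) and the cuticle protein gene Cpr100A (2.17-fold). The aggressive I signal of Obp83b lay near the pseudocount, and its log2 difference ran from -2.92 with values floored at the 1st percentile to -1.71 with the pseudocount at the 25th percentile. The excess on the side of aggressive I shrank with other scaling, to 27 against 18 after quantile normalization and 28 against 20 without centring, and it was gone without aggressive I array 2 and neutral I array 3, with 10 against 11 of 21 calls. It also depended on single arrays of aggressive I, with 19 against 17 without array 1, 14 against 12 without array 2 and 15 against 17 without array 3, which gave 26 and 32 calls without arrays 2 and 3. The count was 28, 23 and 21 without aggressive II arrays 1, 2 and 3, and 30 without neutral II array 2. CG8661, CG13239 and Cpr100A passed in 1, 5 and 2 of the fits without 1 array, and the other 7 genes named here in all 12.

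Between neutral I and neutral II, 23 probe sets passed, 10 higher in I and 13 higher in II. BomS4 (CG18107), a bomanin peptide of the immune response, was 4.68-fold higher in neutral II (51310 ± 2056 against 11260 ± 439.7, SD, n = 3, log2 difference -2.23 for I minus II, SE 0.098, limma adjusted p = 1.22e-06), and Mtk, the antimicrobial peptide metchnikowin, 2.51-fold (6830 ± 631.5 against 2757 ± 181.4). CG5397 was 4.02-fold, Obp99b 2.88-fold (74470 ± 3027 against 26730 ± 1277) and phu, listed with Alp3 among its synonyms, 2.10-fold higher in neutral II. Higher in neutral I were CG3397 (3.39-fold), the cytochrome P450 gene Cyp12d1-d (3.06-fold, 2672 ± 539.4 against 770 ± 52.3), CG42329 (2.86-fold), CG34227 (2.45-fold) and slo, a calcium-activated potassium channel (2.31-fold, 3649 ± 726 against 1472 ± 291.3). With other scaling the balance turned to 15 higher in I and 11 higher in II after quantile normalization, and to 16 and 13 without centring. It was even with values floored at the 1st percentile (10 and 10) and without aggressive I array 2 (12 and 12). The count was 15 without aggressive I array 3, aggressive II array 2, neutral I array 1 or neutral II array 3 and 14 without neutral II array 1. In the same fits slo passed in 3 and Cyp12d1-d in 11 of 12. The within-regime comparisons shared 7 calls, and of the 65 probe sets called in either one, 2 were also called between regimes. The regime fit counts differences between populations of the same regime as error, so a small overlap follows in part from the model.

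The change from neutral to aggressive differed between the I pair and the II pair in 33 probe sets (21 with a larger value in the I pair, 12 with a smaller one, limma interaction). For Obp99b, aggressive I lay above neutral I (log2 difference 0.63) and aggressive II far below neutral II (-3.00), a difference of 3.63 (SE 0.14, adjusted p = 3.45e-07). BomS4 had 0.28 in the I pair and -2.88 in the II pair (difference 3.16, SE 0.14, adjusted p = 5.95e-07), and Mtk 1.98 and -0.26 (difference 2.24, SE 0.17, adjusted p = 0.000173). CG3984 had -3.16 in the II pair, 4.66 below its value in the I pair. CG16926 had 1.34 and -1.80, while Obp83b had -2.13 in the I pair and 0.29 in the II pair. The labels do not state that equal numerals pair populations, and the crossed contrast gave 25 probe sets. With fixed population means, the interaction is the same test as the split of aggressive I and neutral II against the others. The crossed contrast is likewise the same test as the split of I against II. The counts of 33 and 25 are therefore those given above for these splits, not separate results.

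**Figure D4:**
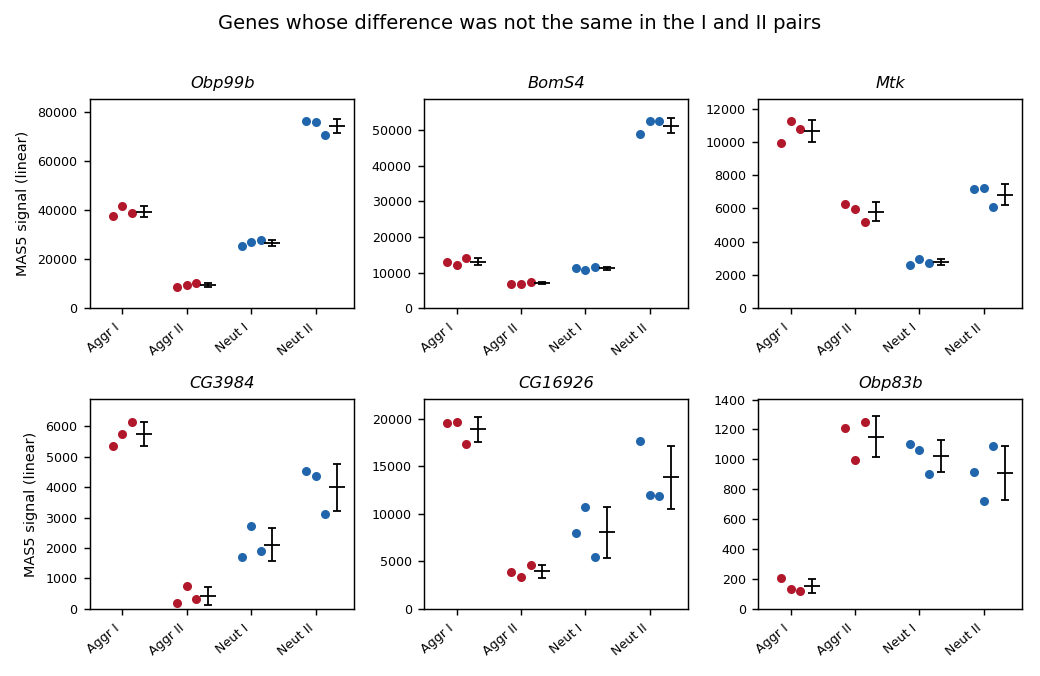
MAS5 signal (linear, y axis from 0) of 6 genes whose aggressive minus neutral difference was not the same in the I and II pairs, in the 4 populations (x axis). Points are single arrays and black marks the mean ± SD of 3 arrays. Obp99b lies between 9460 in aggressive II and 74470 in neutral II, and Obp83b is at 150.9 in aggressive I against 908.9 to 1153 in the other populations.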

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

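Of the tests in this part, the splits of the 12 arrays for called genes, the splits of the 4 populations, the list counts of the other population splits and the test of muscle tissue were chosen after the result had been seen.

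The genes called between aggressive and neutral heads were weighed against chance, drift and hybridization. In 1 of 100 splits of the 12 arrays 6 against 6, the real one, as many genes were called (16, highest other 2), so chance placement of single arrays can be excluded, which says nothing about differences between whole populations. Drift between populations unrelated to the regime stays open and cannot be told apart from selection: 1 of the 3 population splits, the real one, gave as many calls (16, highest other 5), and 3 splits are too few for a share under 0.05. Hybridization conditions, read from the spike-in controls, predicted a median share of -0.0278 of the regime difference of the called genes (95% bootstrap interval -0.0562 to -0.00355), where at least 0.5 was needed. The interval resamples genes that share the same 12 spike-in values, so it leaves out the error these genes share and is too narrow. Called genes were chosen for a regime difference large against their spread, which favours small slopes within populations. A share near 0 was therefore partly to be expected, and hybridization conditions are not excluded. Selection on fighting may account for part of the 16 calls, as a hypothesis, beside drift and hybridization conditions.

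TpnC41C and Mlc1 were among 44 groups of 6 values tested for an array far from the rest, of which chance gives about 1 in 20. TpnC41C was highest in aggressive II array 2, whose gap to the next aggressive array was 0.647 of the range, and Mlc1 was highest among the neutral arrays in neutral I array 2 (0.785 of the range), still below all aggressive arrays. More muscle tissue in the aggressive heads would raise the other muscle markers by about as much as Mlc1 (log2 difference 0.46). Their median was 0.0249 (14 genes, 95% bootstrap interval -0.0277 to 0.157), which argues against a rise of muscle in general as large as that of Mlc1. Mlc1 was chosen for passing and the 14 did not pass, so part of this gap was to be expected. The interval covers the spread between genes, not between arrays or populations, and a smaller rise of muscle is not excluded. A sequence variant under the probes that rose to a high frequency could also change signal. With 0 other probe sets for Mlc1 and TpnC41C it cannot be told apart from a change in transcript level. A change limited to some muscles, or regulation of both genes, stays open and untested.

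The spread of each array about its population mean stood apart for 2 arrays: aggressive I array 2 (gap 0.719 of the range of the 6 aggressive arrays) and neutral I array 3 (0.636 of the range of the 6 neutral arrays). Their residual SDs were 0.272 and 0.281 on the log2 scale, and aggressive I array 2 also had the highest 18S rRNA signal, 38320.

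The aggressive minus neutral difference was not the same in the I and II pairs for 33 probe sets, and 15 of 124 named genes passed this test. Of these, 13 were among the 18 genes named for a large difference within a regime, a quantity the interaction contains, and 2 were among the other 106. The difference of differences, I pair minus II pair on the log2 scale, was 4.66 for CG3984, 3.63 for Obp99b, 3.16 for BomS4, 3.14 for CG16926, 2.24 for Mtk, 1.67 for Pepck2, 1.58 for phu, 1.32 for GstD3 and 1.23 for Cyp4p1. It was -2.43 for Obp83b, -2.19 for slo, -1.62 for CG3397, -1.48 for Sos, -1.17 for CG34227 and -0.73 for CG42329. Permuting the arrays over the populations gave as many calls in 1 of 100 draws, the real one (33, highest other 17), which excludes chance placement of single arrays. With fixed population means, the interaction is the same test as the split of aggressive I and neutral II against the others.

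The 6 genes passing in all 4 population pairs were matched in 1 of 100 permutations, the real one (highest other 0). This excludes chance placement of single arrays and not differences between populations, since the other population splits gave 3 and 2 such genes. As many lists as the 5 called between regimes, with the preset correlation, were called in 3 of 100 splits of the arrays, the real one included (highest other 5). Chance placement of single arrays thus reached the same count, which makes it unlikely as the source but does not exclude it. With population as a random block, the split of aggressive I and neutral II against the others called 7 lists, and with fixed population means 9 against 4 for the regime split. With an estimated correlation it called 1 and 2 lists in these fits, against 0 and 2 for the regime split, so differences between populations unrelated to the regime are not excluded. The correlation of the independent pairs, 0.0071, was reached in 50 of 100 permutations (highest other 0.157), so chance is not excluded. For comparisons of single populations, 10 splits of 6 arrays are too few for a share under 0.05. In each, 1 split of 10, the real one, gave as many calls. The real values were 49 for aggressive I against aggressive II (highest other 2), 23 for neutral I against neutral II (0), 33 for aggressive I against neutral I (0), 98 for aggressive I against neutral II (0). They were 25 for aggressive II against neutral I (1) and 64 for aggressive II against neutral II (1).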

How the results depend on the processing

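Array quality weights, leaving out both arrays that stand apart, and list tests on 1 mean per population or on fixed population means were chosen after seeing the data. The genes called between regimes, Cyp6a20, the genes named within regimes and the 5 lists called were followed under these settings, and none of them reversed direction. Other named genes and lists were not followed in this way. Medians of some lists that did not pass within regimes changed sign without both arrays that stand apart: glia, circadian clock, cuticular hydrocarbon and testis lists between aggressive I and II, and eye pigment and midgut lists between neutral I and II. The balance of higher and lower calls turned in some comparisons of single populations. The 16 calls between regimes became 10 with no filter on dim probe sets, 25 with a filter at the 60th percentile and 35 with a trended and robust variance. They became 68 with fixed population means, 27 with no population term, 0 with 1 mean per population (400 at unadjusted p under 0.05), and 34, 43, 26 and 2 without aggressive I, aggressive II, neutral I and neutral II. They stayed within 1.5 times under other scalings and pseudocounts, array weights (21) and without both arrays that stand apart (15). Aggressive I against aggressive II (49) moved to 27 with no filter, 83 at the 60th percentile, 125 with a trended and robust variance and 21 without both arrays. Neutral I against neutral II (23) moved to 46 at the 60th percentile and 57 with the trended variance, and the interaction (33) to 59 at the 60th percentile. With no filter the pair counts were 21 (aggressive I and neutral I), 43 (aggressive I and neutral II) and 42 (aggressive II and neutral II), and at the 60th percentile 43 (aggressive II and neutral I). Without both arrays they were 16, 55 and 15 (aggressive II and neutral I), and 1 gene passed in all 4 pairs. The lists called (5) became 3 after quantile normalization, 3 with no filter, 0 with an estimated correlation, 2 with 1 mean per population, 4 with fixed population means and 2 with fixed population means and the estimated correlation. A filter changes how many probe sets are tested and the population settings change the error; beyond that the cause was not tested.

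Replicate numbers did not pair arrays: deviations of same-numbered arrays correlated between -0.078 and 0.092, 0 of 18 pairs above 0.1, and 5 of 12 arrays were closest to their own number. With a replicate block there were 7 calls between regimes, 28 and 16 for aggressive I against aggressive II and neutral I, and 51 against neutral II.

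Leaving out 1 array at a time gave 7 to 21 calls between regimes, 21 to 47 and 14 to 24 within the aggressive and neutral regimes, 23 to 33 for the interaction, and 3 to 6 genes in all 4 pairs. It gave 18 to 29, 36 to 96, 13 to 28 and 36 to 59 in the pairs (aggressive I with neutral I and neutral II, then aggressive II), 3 to 7 lists and r from -0.0155 to 0.028, on both sides of 0. The lists fell to 3 without aggressive II array 1, neutral I array 3 or neutral II array 3. Aggressive I against neutral II gave 48, 53 and 57 calls without aggressive I arrays 1, 2 and 3, and 42, 36 and 45 without neutral II arrays 1, 2 and 3. Aggressive I against neutral I gave 19 without aggressive II array 2, aggressive II against neutral I gave 15 without neutral I array 3, and aggressive II against neutral II gave 42 without neutral II array 3. Of the values of single genes between regimes under all alternatives, 324 kept their side of the threshold, 135 lost it and 4 gained it; within regimes 364 kept and 47 lost it, and for lists 87 kept and 33 lost it. Cyp6a20 passed in 4 of 29 alternatives (adjusted p from 0.000791 to 0.974). Dim probe sets are limited by signal over background, which summarised intensities do not give.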

Other observations

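In this part, the list tests within regimes and in the population splits, the tests of a shared factor and of immune genes, and the immune test without BomS4 and Mtk were chosen after the result had been seen.

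Gene lists were also tested between populations of the same regime. With fixed population means, 6 of 24 lists passed between aggressive I and aggressive II, and 4 of these passed with an estimated correlation. Immune effector and recognition genes were higher in aggressive I (43 genes, median log2 difference 0.098, adjusted p = 0.00102, and adjusted p = 0.0459 with an estimated correlation), with BomS4 (0.93), Mtk (0.91), BomBc3 (0.90) and the drosomycin-like Drsl5 (0.57) passing singly. Cytochrome P450 genes (55 genes, median 0.13, adjusted p = 0.023, and 0.0459 with an estimated correlation) were higher in aggressive I, Cyp4p1 by 0.67 and Cyp4ac1 by 0.63. UDP-glycosyltransferases, which conjugate xenobiotics, were also higher (14 genes, median 0.23, adjusted p = 0.023, and 0.0459 with an estimated correlation), and muscle markers were lower in aggressive I (16 genes, median -0.10, adjusted p = 0.0262, and 0.0459 with an estimated correlation). Oxidative phosphorylation (median 0.16, adjusted p = 0.000836) and ribosomal protein genes (median 0.12, adjusted p = 0.0262) were higher in aggressive I with the preset correlation but not with an estimated correlation (adjusted p = 0.43 and 0.685). After quantile normalization 6 lists passed, and these 2 did not (medians 0.078 and 0.039, adjusted p = 0.161 and 0.579), while the immune, P450, UDP-glycosyltransferase and muscle lists passed in the same direction. The other lists that passed there were markers of neurons (median -0.17, adjusted p = 0.0368) and photoreceptor genes (median -0.12, adjusted p = 0.0133), both lower in aggressive I. With an estimated correlation neuron markers passed (adjusted p = 0.04) and photoreceptor genes did not (0.0954), and with the first scaling neither passed (0.137 and 0.259). Without centring 8 lists passed: the 6 of the first analysis in the same direction, and neuron markers (adjusted p = 0.0451) and photoreceptor genes (adjusted p = 0.0456), again lower in aggressive I (0.0457 and 0.144 with an estimated correlation). Without aggressive I array 2 and neutral I array 3, 4 lists passed and 0 with an estimated correlation, the smallest adjusted p there being 0.0702. On the same arrays, 18S rRNA signal was 17640, 38320 and 16620 in aggressive I against 8265, 8785 and 9609 in aggressive II. The 3' to 5' differences of 3 control genes were also larger on average in aggressive I (log2 2.23, 1.27 and 1.90 against 2.01, 0.87 and 1.67). The list differences between these populations are therefore not separated from differences in the RNA samples.

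Between neutral I and neutral II, with all 12 arrays, only oxidative phosphorylation passed, lower in neutral I (median -0.11, adjusted p = 0.0247, and adjusted p = 0.536 with an estimated correlation). It did not pass after quantile normalization (adjusted p = 0.335) or without centring (adjusted p = 0.0817), where 0 lists passed. Without aggressive I array 2 and neutral I array 3, 2 lists passed, oxidative phosphorylation and the immune list, both lower in neutral I (adjusted p = 0.0265 for each), and 0 with an estimated correlation.

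GstD2 and GstD3, neighbouring genes of the same family, moved in opposite directions between regimes, by 0.82 and -0.97 on the log2 scale (limma adjusted p = 0.131 and 0.169). GstD3 signal was 1474 ± 195.7 and 1161 ± 258.3 in aggressive I and II against 1932 ± 207.8 and 3660 ± 204 in neutral I and II (SD, n = 3), and GstD2 signal was 2705 ± 119.5 and 2449 ± 119.9 against 1849 ± 524.2 and 1159 ± 224.7. Whether probes of either gene detect the other was not tested. The difference of these genes was noticed after their values were seen.

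Oxidative phosphorylation and ribosomal protein genes, higher on average in aggressive heads, may follow a factor shared by both lists that varies from array to array. Across the 12 arrays, after taking out population means, the list means correlated with r = 0.726. This shows that the lists vary together between arrays and does not exclude a regime difference as well. The difference of aggressive II minus neutral II was within its SE of 0 for both (oxidative phosphorylation -0.032, SE 0.048, and ribosomal protein 0.0044, SE 0.080). That pair was already known to differ least for both lists, so a value near 0 was to be expected. With population as a random block, the split that puts aggressive I with neutral II called 7 lists (1 with an estimated correlation), against 5 (0) for the regime split and 0 (0) for I against II. With fixed population means these were 9 (2), 4 (2) and 0 (0). A difference in energy or translation genes in aggressive I alone remains open and untested: that population has the highest mean of both lists, and also the highest mean 18S rRNA signal (log2 14.45 against 13.11, 13.20 and 13.22 in aggressive II, neutral I and neutral II), so it is not separated from a difference in the RNA samples.

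Founder haplotypes carried to high frequency by selection or drift could place called genes side by side. Of 57 genes called with fixed population means, 8 had another called gene within 5 measured genes, where random draws of as many genes gave a median of 4 and a 95th percentile of 10 (permutation p = 0.171), so the test between regimes decides nothing. These were CG8157 with Mtk, CG16799 with sktl, atk with Tdh, and GstD2 with GstD3, of which the last 2 pairs are adjacent. Between aggressive I and aggressive II it was 10 of 38 genes (median 2, 95th percentile 6, permutation p = 0.0028), and between the I and II populations 4 of 21 (median 0, 95th percentile 2, permutation p = 0.0307), both more than random draws give. It was 2 of 19 between neutral I and II (permutation p = 0.218) and 0 of 26 for aggressive I and neutral II against the others (permutation p = 1). The comparison of the I and II populations reuses the aggressive arrays, so it is not independent of that between the aggressive populations. These permutation p-values are not adjusted over the comparisons. Haplotypes that differ between the aggressive populations stay open, as does joint regulation of neighbouring genes, which was not tested.

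Immune genes may vary from culture to culture, since BomS4 and Mtk differ between the neutral populations. The mean squared t of the 43 immune genes between neutral I and II, 17.3, lay at percentile 99.87 of 10000 lists matched on signal (median 1.85). The same value was 17.0 between regimes (percentile 99.9) and 8.12 between the aggressive populations (percentile 97.7), so the spread is not particular to populations of the same regime. Without BomS4 and Mtk the value between the neutral populations was 2.62, at percentile 81.9, so the mean rests largely on these genes. They were taken out for their large differences while the matched lists kept theirs, so a lower percentile was to be expected. The median squared t of the list was 0.96, against 0.664 over all genes. A change of the immune response as a whole cannot be told apart from changes at single genes.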
